A study of Arabidopsis thaliana with 12 samples.

How the data were processed

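Total RNA of Arabidopsis thaliana seedlings was measured on 12 one-colour Affymetrix arrays. Seedlings were 9 days old, per the labels' protocols, and were either Col wild type or 35S:LOB-GR. The latter carry LATERAL ORGAN BOUNDARIES (LOB), a transcription factor of organ boundaries, fused to the hormone-binding domain of the glucocorticoid receptor and driven by the constitutive 35S promoter. Such a fusion is held outside the nucleus until a glucocorticoid such as dexamethasone (DEX) is given. Each genotype was kept for 4 h in medium with 5 µM DEX or in medium without it (mock), which gave 4 groups of 3 arrays, labelled as biological replicates.

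The deposited values are log2 expression values, 1 per probe set and array. They were made with RMA, per the submitters' processing notes, and its version is not given in the sources used here. RMA corrects background, sets all arrays to a common distribution and summarises the probes of a set. A shift of most transcripts in one direction would be reduced by that step, and no detection calls were used. The table held 22810 probe sets, of which 64 Affymetrix controls were left out of every test and 22746 were tested. Values ran from 2.71 to 14.14 and array medians from 5.88 to 5.97. The precision is limited by the number of arrays.

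Genes were named from the platform annotation, updated through Entrez identifiers with a RefSeq gene table of assembly TAIR10.1. The annotation gave 1 gene for 13513 probe sets, several for 503 and none for 8730, which are unnamed here. Of the one-gene probe sets, 13436 matched the RefSeq table. They stood for 13355 genes, and 11933 of the probe sets belonged to genes with only a locus name. LOB itself was not among the named genes, so its transcript level was not analysed here. No brassinosteroid biosynthesis gene was among them either.

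Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, without a replicate block, and tested with moderated statistics (eBayes, 8 residual and 6.86 prior degrees of freedom). The contrasts were DEX against mock in each genotype, the difference of those responses, and 35S:LOB-GR against Col under each treatment. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets. A probe set was called at an adjusted p under 0.05. Log2 differences are given with the standard error (SE) of the fit, and group levels as mean ± SD of 3 arrays.

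The genes named in the text follow a rule written before the data were examined, as were the groups, the tests, the 26 gene lists and the alternatives. For DEX in 35S:LOB-GR the rule took the 12 rises and the 12 falls with the largest absolute log2 change. For the other comparisons it took 6 in each direction, or fewer where fewer passed. It required 1 gene per probe set, a call and, except for the difference of responses, all 3 arrays of one group above all 3 of the other. Measured brassinosteroid biosynthesis and inactivation genes were added, with up to 4 members of each list described, those of largest change.

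Lists were tested with limma's camera, a competitive test against all other genes, with a preset inter-gene correlation of 0.01. Each gene was represented by its brightest probe set. Of the 26 lists, 4 had 3 or more measured genes and were tested, 16 had 1 or 2 and 6 had none. Another 20 lists were chosen after the annotation was seen and before any test was run, and were adjusted among themselves. Camera with an estimated correlation and fry were run as alternatives.

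The fit was tested on simulated data with 200 changed among 22746 probe sets. For DEX in 35S:LOB-GR it recovered 70.1% of changes of 0.5 on the log2 scale and 100% of changes of 1, with 15 false calls. For the difference of responses it recovered 16.4% of changes of 0.5 and 92.5% of changes of 1, with 6 false calls. For the genotype difference under mock these shares were 61.2% and 98.5%, with 12 false calls. Camera called the 1 shifted list among 26 simulated lists of 8 genes and no other. The simulated genes were uncorrelated, so this run does not bear on lists whose genes vary together. Estimated correlations in the real data were 0.249 for alpha-expansins, 0.271 for stomatal lineage genes and 0.15 for xyloglucan endotransglucosylases. For auxin response genes the estimate was -0.031, under the preset 0.01. Their camera p for DEX in 35S:LOB-GR still rose from 0.0116 to 0.031 with it. A call lost with an estimated correlation is therefore not by itself a sign that the genes vary together.

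Alternatives included another normalization, a filter on dim probe sets, other spread estimates, array weights, stricter thresholds, a replicate block and each array left out in turn. The neighbours of genes were taken from TAIR10.1. No coordinates are given because the files used here name no build.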

Results

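Transcript levels were measured in seedlings of 2 genotypes, Col and 35S:LOB-GR, each kept in mock medium or in 5 µM DEX for 4 h. There were 3 arrays in each of the 4 groups. Arrays of one group correlated at 0.9922 or higher (Pearson, across probe sets, which are not independent replicates). The first principal component held 48.8% of the variance and separated the genotypes. The second held 16.2% and separated mock from DEX arrays in both genotypes. In 35S:LOB-GR the mock arrays lay at 13.8 or higher and the DEX arrays at -10.7 or lower, and in Col at -2.6 or higher and at -6.8 or lower. The first DEX replicate of 35S:LOB-GR lay farthest from its group mean, with a root mean square deviation of 0.166 on the log2 scale.

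**Figure D1:**
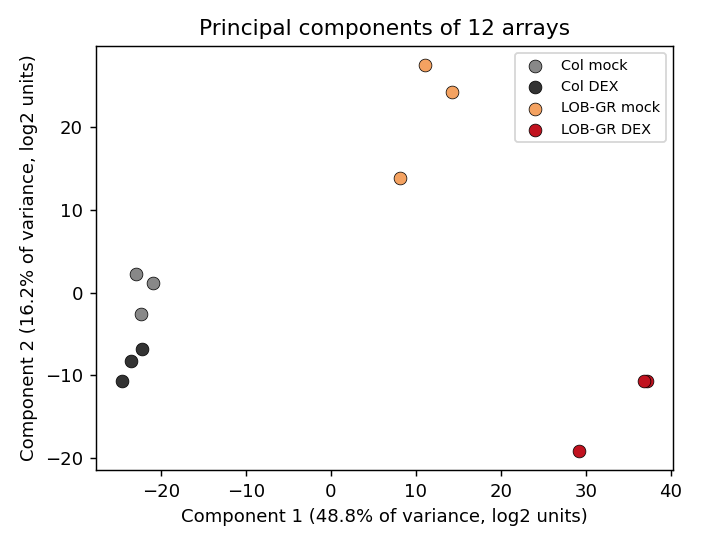
First and second principal components of the 12 arrays, in log2 units, with 1 point per array coloured by group. The Col arrays lie between -24.6 and -21.0 on component 1, and the 35S:LOB-GR arrays between 8.1 and 37.2.

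The response to DEX in 35S:LOB-GR asks which transcripts change once the LOB fusion is activated. The largest named rises included 1 expansin, and the largest named falls included another expansin and a pectin methylesterase. EXPA9, an expansin that loosens cell walls, rose from 6.59 ± 0.08 to 8.42 ± 0.23 (log2, SD, n = 3), a change of 1.83 ± 0.12 (SE) with a limma adjusted p of 1.77e-07. Another expansin, EXPA8, fell by 2.06 ± 0.23 (limma adjusted p = 2.86e-05). ATPMEPCRB, a pectin methylesterase also called PME41, fell by 2.96 ± 0.26, from 8.97 ± 0.60 to 6.01 ± 0.16 (limma adjusted p = 2.37e-06). BAT1, an acyltransferase that inactivates brassinosteroids, rose by 0.77 (limma adjusted p = 3.57e-05).

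Among the largest rises were 2 genes of unknown function, AT5G57785 at 2.18 ± 0.17 and AT1G64405 at 1.86 ± 0.12. AT3G51660, related to macrophage migration inhibitory factor, rose by 1.90 ± 0.14, and AT3G13672 (SINA2) by 1.83 ± 0.18. AT1G48330 rose by 1.76 and AT5G47610, a RING finger protein, by 1.65. The MYB-like gene AT1G70000 rose by 1.63, and AT1G33170, a predicted methyltransferase, by 1.58. AT2G19970 rose by 1.51 and AT3G08030, a cell wall protein of the DUF642 family, by 1.49. The lipid transfer protein-like AT3G18280 rose from 8.26 ± 0.06 to 9.76 ± 0.20 (SD, n = 3). Limma's adjusted p lay between 1.77e-07 for EXPA9 and AT3G08030 and 0.000341 for AT2G19970. All 3 DEX arrays exceeded all 3 mock arrays for each of these genes, which the naming rule required.

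Large falls included AT5G62280, which fell by 2.84 ± 0.23, and AT4G22470, a lipid transfer protein-like gene, which fell by 2.66 ± 0.13. The class III peroxidase AT5G39580 fell by 2.43 ± 0.19. Genes of the acyltransferase family AT5G01210 (-2.40) and AT2G39980 (-2.02) fell, as did AT3G19850 (-2.40) of the NPH3 family. The leucine-rich repeat receptor kinases AT1G51850 (-2.15) and AT4G34220 (-2.13) fell as well. In Col AT1G51850 was at -0.91, not called, and its DEX responses were not called different (limma adjusted p = 0.104 for the difference). AT3G46280 fell by 2.04, as did AT5G50335. Limma's adjusted p was 0.000137 for AT1G51850 and lower for the others.

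Of the 8 alpha-expansins measured from a list of 18, 3 rose, 1 fell and 4 were not called. The risers were EXPA9, EXPA4 at 1.39 ± 0.09 and EXPA20 at 0.41 ± 0.09. Adjusted over the list alone, 4 rose and 1 fell. This list shifted up, with a median change of 0.23 (camera adjusted p = 0.00364, and adjusted p = 0.116 with an estimated correlation). No shift was called over all expansin classes, a list chosen after the annotation was seen: of 18 measured genes 4 rose and 5 fell, with a median of 0.04 (camera adjusted p = 0.666). EXPB3 (0.95) also rose, and EXLA1 (-0.82), EXLA2 (-0.65), EXLB1 (-0.63) and EXPB1 (-0.38) also fell.

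Xyloglucan endotransglucosylases, which remodel wall xyloglucan, shifted down (camera adjusted p = 5.96e-05, and adjusted p = 0.0621 with an estimated correlation). Of the 9 measured from a list of 27, 4 fell and 5 were not called, also when adjusted over the list alone. The members that fell were XTH16 (-1.29 ± 0.11), XTH18 (-1.04 ± 0.28), XTH20 (-0.91 ± 0.10) and XTH19 (-0.55 ± 0.16).

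Of 8 auxin response genes measured from 22, 2 fell and 6 were not called, also when adjusted over the list alone. The ones that fell were GH3.3 (-1.53 ± 0.25) and WES1 (GH3.5; -0.70 ± 0.15), both of which encode enzymes that conjugate auxin to amino acids. IAA29 was at -0.33 (limma adjusted p = 0.192) and IAA30 at -0.16 (limma adjusted p = 0.352). The list shifted down (camera adjusted p = 0.0154, and adjusted p = 0.0621 with an estimated correlation).

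Of the 3 stomatal lineage genes measured from 7, SPCH, which starts the lineage, fell by 0.43 ± 0.12 (limma adjusted p = 0.0306). Adjusted over the list alone 1 fell as well. FMA (FAMA) was at -0.27 and MUTE at -0.04, neither called. The list's camera adjusted p of 0.0401 became an adjusted p of 0.133 with an estimated correlation. It was 0.0524 without mock replicate 1 of 35S:LOB-GR, 0.0772 without its mock replicate 2 and 0.105 without its DEX replicate 1.

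Other lists had only 1 or 2 measured genes and were not tested as groups. BRL1, a brassinosteroid receptor, rose from 3.79 ± 0.03 to 5.08 ± 0.08, by 1.29 (limma adjusted p = 1.77e-07). Its mock level was near the low end of the values, the lowest of which was 2.71, and no detection calls were used, so the size of the change in BRL1 is less certain and can be compressed by background. The same limit holds for AT3G13672 (4.12 under mock in 35S:LOB-GR), PDF2.5 (3.94 under DEX in Col) and COR15A (4.23 under mock in Col). The cytokinin response regulators ARR15 (-0.44, limma adjusted p = 0.0216) and RR16 (-0.39, limma adjusted p = 0.0346) fell. ARR15, at 3.83 under DEX in 35S:LOB-GR, was also near the low end of the values. Levels of the LOB-domain genes LBD16 and LBD29 were at -0.07 and 0.03, and that of the boundary gene LAS at -0.14, none of them called. The leaf marker RCA was at -0.10 and the root hair expansins EXPA7 and EXPA18 at 0.14 and 0.05, also not called.

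In total 2267 probe sets were called for DEX in 35S:LOB-GR by limma, 904 higher and 1363 lower, and 323 of them changed at least 2-fold. The 3 DEX and 3 mock arrays did not overlap for 2200 of the called probe sets, and for 22.8% of all probe sets, where chance gives 10%. The share of higher calls was 39.9%, and 53.0% (1311 higher, 1163 lower) once each array's median was subtracted. Fitting only the 6 arrays compared left 1500 calls. The largest rise, 3.24, and the largest fall, -3.02, belonged to unnamed probe sets.

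**Figure D2:**
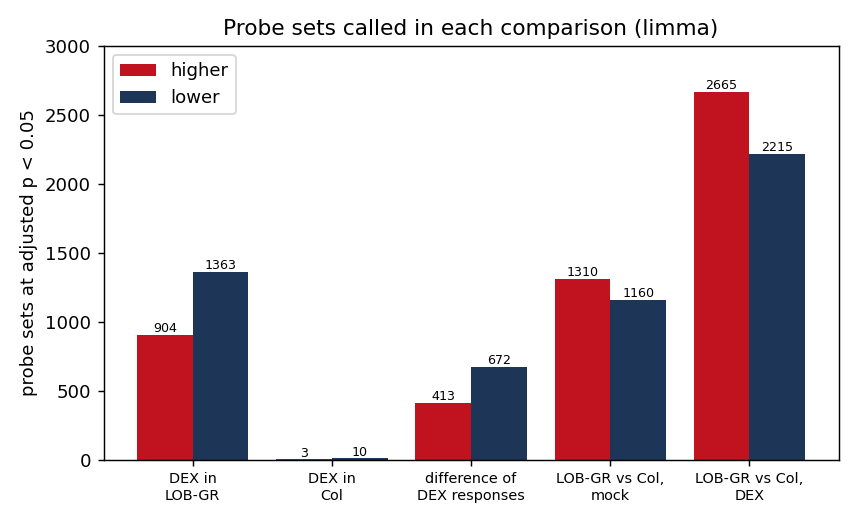
Number of probe sets at a limma adjusted p under 0.05 in each comparison, higher (red) and lower (blue), out of 22746 tested. DEX changed 904 and 1363 in 35S:LOB-GR, and 3 and 10 in Col.

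The response to DEX in Col compares DEX with mock medium without the fusion. COR27, a cold- and clock-regulated gene, rose from 5.26 ± 0.29 to 6.50 ± 0.04, by 1.24 ± 0.13 (limma adjusted p = 0.00126). AT2G19310, a small heat shock-like gene, rose by 0.73 ± 0.12 and AT5G62960 by 0.57 ± 0.09. The plastid ribosomal protein gene rpl14 fell by 1.14 ± 0.18 (limma adjusted p = 0.0330) and AT3G57930 fell by 0.82 ± 0.09 (limma adjusted p = 0.00126). The kinesin gene AT2G36200 (-0.79), the cation exchanger gene CHX16 (-0.71), the defensin gene PDF2.5 (-0.66) and the late embryogenesis abundant gene AT2G23120 (-0.64) fell too.

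Auxin response genes shifted up as a list in Col (median 0.21, camera adjusted p = 0.00544, and adjusted p = 0.0425 with an estimated correlation). Single members were not called over all probe sets, and 1 of 8 rose when adjusted over the list alone. The largest values were 0.94 ± 0.25 for GH3.3 (limma adjusted p = 0.132) and 0.41 for WES1 (limma adjusted p = 0.267). For expansins, xyloglucan endotransglucosylases and stomatal lineage genes the camera adjusted p was 0.263, 0.263 and 0.526, and for all expansin classes it was 0.113.

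Limma called 13 probe sets in Col, 3 higher and 10 lower, and 2886 had an unadjusted p under 0.05. The 3 DEX and 3 mock arrays of Col did not overlap for 21% of all probe sets, where chance gives 10% and 35S:LOB-GR gave 22.8%. After median subtraction 17 were called, 7 of them higher. The number of calls moved widely. It was 407 when only the 6 Col arrays were fitted, 141 without DEX replicate 1 of 35S:LOB-GR, whose spread enters the pooled estimate, and 2 without mock replicate 1 of Col. COR27 and AT3G57930 stayed called with any 1 Col array left out, and the calls of the other named genes each ended with some array left out. The 3' minus 5' difference of the actin control probe sets was 1.22 ± 0.18 in the mock and 0.95 ± 0.06 in the DEX arrays of Col (log2, SD, n = 3).

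The DEX responses of the genotypes were weakly related across probe sets, with a Pearson r of 0.111 and a Spearman rho of 0.11. They share no array, and probe sets are not independent replicates. Without DEX replicate 1 of 35S:LOB-GR r was 0.022, and without its mock replicate 1 it was 0.05. Over the 2267 probe sets called in 35S:LOB-GR it was 0.165.

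**Figure D3:**
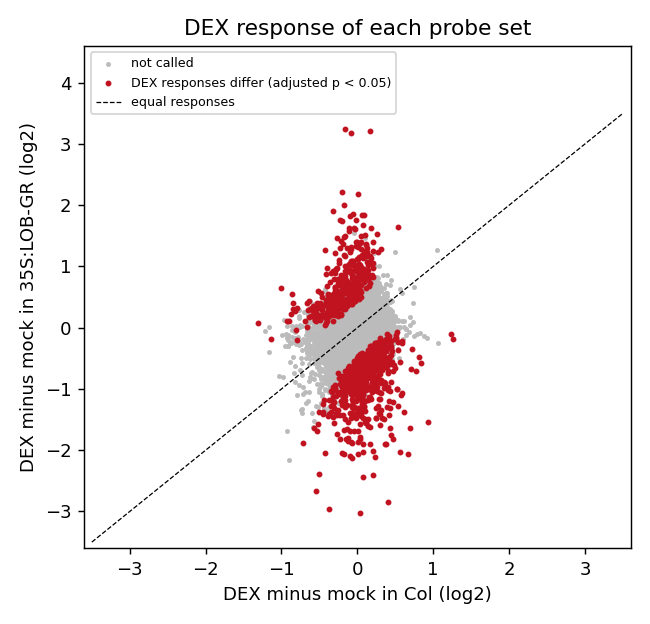
DEX minus mock (log2) of each of the 22746 probe sets in Col (x axis) and in 35S:LOB-GR (y axis), with those whose responses differed at a limma adjusted p under 0.05 in red (1085) and equal responses as a dashed line. Red points spread along the y axis.

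The difference of the responses tests which DEX effects depended on the transgene. The response of EXPA9 was higher in 35S:LOB-GR by 1.74 ± 0.16 (limma adjusted p = 2.08e-05), and that of EXPA8 was lower, at -2.73 ± 0.33 (limma adjusted p = 0.00015). AT3G51660, AT5G57785, AT3G13672, AT1G64405 and AT1G48330 had responses higher by 1.77 to 2.23. AT5G62280 (-3.24), AT5G01210 (-2.61), AT5G50335 (-2.60), ATPMEPCRB (-2.59) and AT5G39580 (-2.50) had lower ones. BAT1 differed by 0.80 (limma adjusted p = 0.00145) and BRL1, which was near the low end of the values without DEX, by 1.23 (limma adjusted p = 1.91e-05).

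Among auxin response genes, 2 of 8 had a lower response in 35S:LOB-GR and 3 when adjusted over the list alone. They included GH3.3 at -2.47 ± 0.35 and WES1 at -1.11 ± 0.21. The list differed with both correlations (camera adjusted p = 0.000526, and adjusted p = 0.0168 with an estimated correlation). Alpha-expansin responses were higher as a list, with EXPA9 and EXPA4 higher and EXPA8 lower, the same 3 genes as when adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.181 with an estimated correlation). Over all expansin classes 3 of 18 responses were higher and 4 lower, with a median of 0.08, a mean of -0.06 and a camera adjusted p of 0.966 (Down). Xyloglucan endotransglucosylase responses were lower, with XTH16 at -1.22 and XTH20 at -0.73 called, and 3 lower when adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.0936 with an estimated correlation). Stomatal lineage genes gave a camera adjusted p of 0.153.

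Limma called 1085 probe sets for the difference, 413 higher and 672 lower in 35S:LOB-GR, and 329 of them at least 2-fold.

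**Figure D4:**
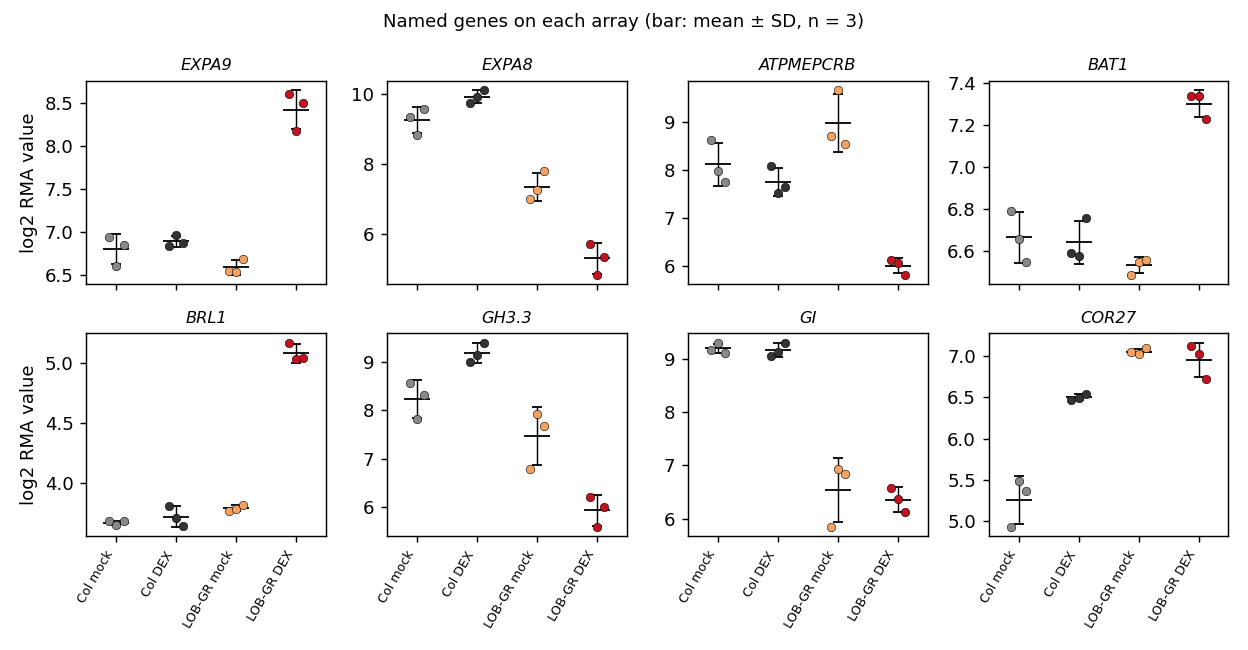
Log2 RMA values of 8 named genes on each array, by group, with the mean and SD of 3 arrays as a bar and whiskers. EXPA9, BAT1 and BRL1 rise with DEX in 35S:LOB-GR, EXPA8, ATPMEPCRB and GH3.3 fall there, and GI is lower in all 35S:LOB-GR arrays than in all Col arrays.

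The genotypes were compared under mock to see what the transgene changed without DEX. GI (GIGANTEA), a clock gene of the evening, was lower in 35S:LOB-GR, at 6.54 ± 0.60 against 9.19 ± 0.09 in Col, a difference of -2.65 ± 0.21 (limma adjusted p = 1.02e-06). AT3G15450, a gene known to rise under sugar starvation, was lower by a log2 difference of -2.31 ± 0.20. AT5G35970 (-2.14), AT2G32150 (-2.13) and the thionin gene AT1G66100 (-2.12) were lower as well. The RING finger gene AT5G19430 was lower as well (limma adjusted p = 4.16e-09), at a level of 3.90 ± 0.13 in 35S:LOB-GR, near the low end of the values, so the size of its difference is less certain. The cold-regulated genes COR15A and COR27 were higher, by 2.25 ± 0.45 (limma adjusted p = 0.00398) and 1.79 ± 0.13 (limma adjusted p = 3.95e-07). So were AT2G23910 (2.39), AT3G28270 (2.18), the small heat shock gene AT2G29500 (2.16) and the ATPase gene AT1G43910 (2.11).

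Some wall genes differed under mock as well. EXPA8 was lower in 35S:LOB-GR by a log2 difference of -1.91, and EXPA16 (1.23), EXPA20 (0.80) and EXPA4 (0.34) were higher, 3 of 8 alpha-expansins higher and 1 lower, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.293). Over all expansin classes 4 of 18 were higher and 2 lower (camera adjusted p = 0.94). XTH19 (-1.02), XTH16 (-0.58), EXGT-A3 (-0.39) and XTH20 (-0.33) were lower, 4 of 9 also when adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.221 with an estimated correlation). In the auxin response list IAA29 (-1.49) and WES1 (-0.64) were lower, 2 of 8, or 3 when adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.0812 with an estimated correlation). Stomatal lineage genes gave a camera adjusted p of 0.589.

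Limma called 2470 probe sets under mock, 1310 higher and 1160 lower in 35S:LOB-GR, and 273 at least 2-fold. The 3 arrays of each genotype did not overlap for 2435 of the called probe sets, and for 27.9% of all probe sets, where chance gives 10%. The largest differences, 4.05 and -5.25, belonged to unnamed probe sets. The labels give no batch, sowing or harvest, so these cannot be separated from genotype. The 3' minus 5' difference of the GAPDH control probe sets was -0.17 ± 0.07 in Col and -0.36 ± 0.09 in 35S:LOB-GR under mock (log2, SD, n = 3).

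Under DEX the genotypes differed more widely. EXPA8 showed the largest named difference, 5.29 ± 0.44 in 35S:LOB-GR against 9.93 ± 0.19 in Col, or -4.64 ± 0.23 (limma adjusted p = 2.88e-09). AT5G62280 was at -4.27, GH3.3 at -3.23, AT3G13980 at -2.91, GI at -2.80 and AT4G34220 at -2.72. Higher in 35S:LOB-GR were AT3G28270 (2.42), AT2G23910 (2.36), AT1G70000, AT3G13672, the cytochrome P450 gene AT3G44970 and AT1G47400 (2.15), a peptide gene of the iron deficiency response. BAT1 was higher by 0.66 and BRL1 by 1.36.

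Of 8 alpha-expansins, 5 were higher and 1 lower, or 5 and 1 when adjusted over the list alone (camera adjusted p = 0.000772, and adjusted p = 0.0852 with an estimated correlation). EXPA4 (1.69), EXPA9 (1.53) and EXPA20 (1.08) led the higher ones. Over all expansin classes 6 of 18 were higher and 5 lower, with a median of 0.05, a mean of -0.11 and a camera adjusted p of 0.862. Xyloglucan endotransglucosylases were lower in 5 of 9 cases, also when adjusted over the list alone, led by XTH16 (-1.80), XTH19 (-1.10), XTH20 (-1.06) and XTH33 (-0.64). Auxin response genes were lower in 4 of 8 cases, also when adjusted over the list alone, namely GH3.3, IAA29 (-2.12), WES1 (-1.75) and LBD16 (-0.35). The xyloglucan endotransglucosylase and auxin response lists were called with the preset correlation (camera adjusted p = 3.75e-05 for both) and held with an estimated one (adjusted p = 0.034 and 0.00719). Stomatal lineage genes gave a camera adjusted p of 0.336.

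Limma called 4880 probe sets under DEX, 2665 higher and 2215 lower in 35S:LOB-GR, and 709 at least 2-fold. The arrays of the genotypes did not overlap for 4717 of them, and for 33.9% of all probe sets, where chance gives 10%. The 3' minus 5' difference of the actin control probe sets ran from 0.90 to 1.02 in Col and from 1.06 to 1.17 in 35S:LOB-GR under DEX (log2), and that of GAPDH was -0.21 ± 0.08 and -0.32 ± 0.05 (log2, SD, n = 3). Genotype differences under mock and under DEX, which share no array, correlated at 0.608 across probe sets (Spearman 0.459). Of the probe sets higher under mock, 718 were also higher under DEX, where independent lists of those sizes would share 153.5, and of those lower under mock, 756 were also lower, against 113. Opposite directions were called for 47 and 29.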

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

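The tests of DEX itself and of fusion activity without DEX, the range over arrays left out for the clock-regulated genes, and the use of the cold-regulated and carbon starvation lists beside other explanations or comparisons, were chosen after the results they bear on had been seen. The responses to DEX differed between the genotypes, by the test of the difference itself, for 1085 probe sets (4.77%) and for 3 gene lists. They also differed for 30 of the 34 genes named for the DEX comparisons. Most of these genes were picked for large changes or calls on the same arrays, so this share is raised by the choice. Not called were AT1G51850, AT2G19310, AT5G62960 and CHX16. The lists were alpha-expansins (camera adjusted p = 0.0106, but 0.966 over all expansin classes), xyloglucan endotransglucosylases (0.00163) and auxin response genes (0.000526), and only the last held with an estimated correlation.

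Among genes that rose in 35S:LOB-GR, the log2 response exceeded that in Col by 2.23 for AT3G51660, 2.17 for AT5G57785, 1.93 for AT3G13672, 1.92 for AT1G64405, 1.77 for AT1G48330 and 1.74 for EXPA9. It exceeded it by 1.69 for AT1G33170, 1.67 for AT1G70000, 1.66 for AT3G18280, 1.45 for AT3G08030, 1.41 for AT2G19970, 1.12 for AT5G47610 and 0.80 for BAT1. Among genes that fell there, the difference was -3.24 for AT5G62280, -2.73 for EXPA8, -2.61 for AT5G01210, -2.60 for AT5G50335, -2.59 for ATPMEPCRB and -2.50 for AT5G39580. It was -2.22 for AT2G39980, -2.12 for AT4G22470, -2.07 for AT4G34220, -1.88 for AT3G19850 and -1.84 for AT3G46280. Genes called in Col also differed, at -1.34 for COR27, 0.96 for rpl14, 0.81 for AT2G23120, 0.77 for AT3G57930, 0.68 for PDF2.5 and 0.60 for AT2G36200. A shift of the Col mock arrays alone would give such differences too.

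Relabelling DEX and mock within each genotype gave as many calls for the difference in 2 of 100 relabellings, the real one (1085) included, and the highest other count was 1674. That relabelling exchanged the arms of one genotype only, so it adds the responses where the real one subtracts them. The 10 relabellings that kept the arms of 35S:LOB-GR gave 718 or more, and the 90 that mixed them gave at most 16. The relabellings thus mostly follow the response of 35S:LOB-GR and say little of the Col part. The share of 2 in 100 therefore does not decide whether the difference of responses arose by chance.

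The 2267 probe sets called for DEX in 35S:LOB-GR could reflect DEX itself. The values argue against this as the main source, since DEX alone would need about equal responses. Over these probe sets the Col response had a slope of 0.051 on the 35S:LOB-GR response, and 56.9% had the same sign. The slope was 0.037 to 0.066 over resampled probe sets, a range that leaves out the spread between arrays. With 1 array left out, the correlation of the responses over all probe sets ran from 0.022 to 0.176. A shift of clock phase between mock and DEX plates stays open, since 10 clock-regulated genes lay at the 71.2 percentile of matched random lists, and between 20.6 and 96.5 with 1 array left out. Each 3 against 3 comparison has 10 splits, too few for a share under 0.05. The real count here was 2267 and the highest other 1.

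Activity of the fusion without DEX could give the 2470 mock differences. If in proportion to the response to 4 h of DEX, it is argued against as their source as a whole. With no array shared, the mock difference and the DEX response correlated at no more than 0.088 across probe sets. The values were -0.015, 0.013 and 0.088 over the 3 ways to part the mock arrays. Of the 500 largest responders, 46.2% to 54% had the same sign. Activity that had already brought transcripts close to their DEX level would leave little response, so these correlations cannot decide on it. Activity without DEX also stays open for a part. Called higher in both were 82 probe sets, and lower in both 209, such as EXPA8 (-1.91 under mock, -2.06 with DEX). Independent lists of those sizes would share 52.1 and 69.5. In opposite directions 93 and 263 were called, against 46.1 and 78.5, such as AT3G51660 (-1.12, 1.90) and ATPMEPCRB (0.85, -2.96). Mock arrays shared with opposite sign favour these opposite directions. A difference in clock phase stays open: the median absolute difference of 10 clock-regulated genes, chosen without GI and COR27, was 0.60, at the 100 percentile of 10000 matched random lists, but the cold-regulated list (0.49) and the carbon starvation list (0.52) lay there too, so this does not single out the clock. A difference in carbon or light status is consistent with a median of -0.52 over 8 carbon starvation genes (camera p = 9.51e-09, and p = 0.00818 with an estimated correlation), and within 35S:LOB-GR the list was also lower with DEX, at -0.23 (p = 0.0026, and p = 0.104 with an estimated correlation), and its response was lower than in Col, at -0.37 (p = 0.000217, and p = 0.0546). A genotype batch does not enter the comparison within 35S:LOB-GR, so action of the transgene on these genes may contribute, while growth and harvest stay open for the mock difference, where genotype and any batch go together and 10 splits are too few for a share under 0.05 (real 2470, highest other 1).

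For DEX in Col and for the genotypes under DEX the 10 splits are likewise too few. In each, 1 split, the real one, gave as many calls (real 13 and 4880, highest other 0 in both).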

How the results depend on the processing

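Every alternative here was planned before the data were examined. Counts of calls stayed within 1.5 times under quantile normalization, median subtraction, trended or robust spread estimates, array weights and the filter on the 30% dimmest probe sets, except in Col. With the order DEX in 35S:LOB-GR, difference of responses, genotype under mock and genotype under DEX, one-gene probe sets alone gave 1166, 473, 1130 and 2503 calls. An adjusted p under 0.01 gave 1299, 474, 1308 and 3018, and a 2-fold minimum gave 323, 329, 273 and 709. These are fewer by construction. Fitting only the compared arrays gave 1500 for DEX in 35S:LOB-GR. With 1 array left out the counts ran from 1705 to 2324, 724 to 1591, 1751 to 2925 and 3592 to 5440, each highest without DEX replicate 1 of 35S:LOB-GR.

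The count for DEX in Col, 13, was 30 without the dimmest probe sets, 50 with an intensity trend, 42 with trend and robust estimates, 399 with array weights and 407 with only the Col arrays, each holding at least 12 of the 13. It was 2 at an adjusted p under 0.01 and 3 with a 2-fold minimum. Leaving out 1 array gave 2 to 141: 2 without Col mock replicate 1 or any 1 of the Col DEX replicates, 5 without Col mock replicate 2, 69 without Col mock replicate 3, 20 to 24 without mock replicate 2 or 3 or DEX replicate 2 or 3 of 35S:LOB-GR, and 141 without its DEX replicate 1. The weight of noisier 35S:LOB-GR arrays in the pooled spread is a candidate source, in line with the 407. Otherwise the cause was not tested.

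The correlation of the DEX effects, 0.111, ran from 0.022 to 0.176 with 1 array left out, and was 0.05 without mock replicate 1 of 35S:LOB-GR. Of the 4 lists called for DEX in 35S:LOB-GR, 0 held with an estimated correlation in camera, and fry called 4. With 1 array left out 3 to 4 lists were called.

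Replicate numbers did not pair the samples. Same-numbered arrays of different groups had residual correlations of -0.23 to 0.19, 2 of 18 over 0.1, and 2 of 12 arrays correlated best with one of their own number. A replicate block gave 8 calls for DEX in Col, and changed no other count by over 1.5 times. It ended the calls of 4 named genes in Col.

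Of 772 alternative values for 70 pairs of named gene and comparison, none reversed and 39 lost the call, all for 7 genes in Col. These pairs were the genes of largest change in each comparison, with BAT1. Genes named only as members of other lists, such as SPCH, ARR15, RR16, XTH18, XTH19 and WES1, were not run. The level of LOB was not run because no probe set here names it. Dim probe sets have no detection calls here, so small changes near background are limited.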

Other observations

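The gene families below were chosen after the annotation was seen and before any test. In 35S:LOB-GR under DEX, 8 of 47 UDP-glycosyltransferase genes fell, led by UGT74D1 (-1.21), UGT84A3 (-1.08), UGT87A2 (-0.82) and UGT76C2 (-0.74), and the family shifted down (camera adjusted p = 0.000165, and adjusted p = 0.0635 with an estimated correlation). Of 15 IQ-domain genes, whose proteins bind calmodulin and microtubules, 5 fell, among them IQD19 (-0.71), IQD23 (-0.69), iqd21 (-0.49) and IQD28 (-0.47), with a camera adjusted p of 0.00062 (adjusted p = 0.0918 with an estimated correlation). Of 20 beta-glucosidase genes 4 fell, led by BGLU40 (-0.82), BGLU33 (-0.80) and BGLU44 (-0.75), but the family median of -0.04 turned to 0.002 after median subtraction (camera adjusted p = 0.0461, and adjusted p = 0.145 with an estimated correlation). Cytosolic ribosomal protein genes shifted up by a median of 0.13, with 2 of 68 called, AT3G11250 (0.36) and AT2G36160 (0.28) (camera adjusted p = 7.97e-05, and adjusted p = 0.497 with an estimated correlation). Their list held no loci of chromosomes 4 and 5, so it covers only a part of the family.

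Under mock, 7 of 47 UDP-glycosyltransferase genes were higher in 35S:LOB-GR, led by UGT78D2 (1.29), UGT71B1 (1.24), UGT78D1 (1.05) and UGT87A2 (0.89), and UGT78D1 and UGT78D2 encode flavonol glycosyltransferases (camera adjusted p = 0.00527, and adjusted p = 0.166 with an estimated correlation). This and the fall of the family with DEX rest on the same 3 mock arrays of 35S:LOB-GR, with opposite sign, and UGT87A2 is in both. Under DEX 8 of 47 were higher and 5 lower, with a median of -0.01 (camera adjusted p = 0.862). Cytosolic ribosomal protein genes of the partial list above were higher too, 2 of 68 under mock and 19 of 68 under DEX (camera adjusted p = 0.00527 and 2.81e-08, and adjusted p = 0.969 and 0.606 with an estimated correlation).

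In Col, the median change of 69 chloroplast-encoded genes under DEX was -0.21, with 14 of them above 0, rpl14 (-1.14) called and rpl16 (-1.16), rps19 (-0.95) and rpoA (-0.93) not (camera adjusted p = 2.81e-11, and adjusted p = 0.335 with an estimated correlation). Their median per array was 10.04, 10.02 and 9.94 in the Col mock arrays and 9.71, 9.76 and 9.85 in the Col DEX arrays, and ran from 9.71 to 10.46 in 35S:LOB-GR. The actin 3' minus 5' difference, 1.22 ± 0.18 and 0.95 ± 0.06, moved with them.

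Hypotheses on the mock difference were tested on genes other than those that prompted them. If COR15A and COR27 marked a cold response shared by cold-regulated genes in general, others would be higher too. The median of 8 was 0.049 with an SD of 0.55 over the members, which argues against a rise common to all 8. The rise to be expected of each member is not known here, so these genes cannot decide on a cold response of only some genes. Of these cold-regulated genes LTI30 (-0.70) was lower and AT4G12000 (0.55) higher. COR15B (0.94, limma adjusted p = 0.0546), the largest difference, and COR47 (-0.52, limma adjusted p = 0.0563) were not called. Adding BETA-VPE (AT1G62710), which was done after the values had been seen, gave a median of -0.063. If a linked chromosome segment carried the difference, genes at least 2-fold different in the same direction under both treatments would be neighbours. Of 76 such genes, 19 higher and 57 lower, 1 pair lay within 3 measured genes of each other, AT5G57340 and AT5G57345, and random gene sets gave a median of 1 (permutation p = 0.73).

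In the clock-regulated list, AT1G56300 (-1.30), AT1G69570 (-0.77) and AT2G15880 (-0.77) were lower under mock and AT4G33980 (0.72) higher, 4 lower and 2 higher in all. In the carbon starvation list 6 of 8 were lower, led by AT2G30600 (-1.22), ATL8 (-0.87), AKINBETA1 (-0.69) and AT1G18460 (-0.54). With DEX in 35S:LOB-GR, AT2G30600 (-0.85) and ATL8 (-0.74) fell.

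Further families were called by camera with the preset correlation and not with an estimated one. For DEX in Col these were TRM1-related genes (camera adjusted p = 0.0407), class III peroxidases (0.032) and tau glutathione transferases (0.0407), each with an adjusted p of 0.335 with an estimated correlation. For the difference of responses they were IQ-domain genes (0.02), UDP-glycosyltransferases (0.0245), chloroplast-encoded genes (0.00982) and cytosolic ribosomal proteins (0.00448), with adjusted p of 0.32, 0.32, 0.772 and 0.772 with an estimated correlation. IQ-domain genes were lower in 35S:LOB-GR under DEX, 5 of 15 of them (camera adjusted p = 0.000854, and adjusted p = 0.179 with an estimated correlation). Fry, which does not compare a list with other genes, also called TRM1-related genes in Col (adjusted p = 0.043) and IQ-domain genes under DEX (0.000739). It did not call class III peroxidases (fry adjusted p = 0.243) or tau glutathione transferases (0.0858) in Col. Nor did it call the families named for the difference of responses (0.102 for IQ-domain genes and UDP-glycosyltransferases, and higher for the others).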
